A study of Mus musculus with 2 samples.

How the data were processed

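Colon tumour tissue of mice was profiled by single-cell RNA sequencing in 2 libraries, 1 per genotype. One library is labelled KO, from animals with floxed Ecm1 alleles and Cre recombinase driven by the Villin promoter, which acts in intestinal epithelium. The other is labelled WT, from animals with the floxed alleles and no Cre. The number of animals behind each library, the tumour model, the sex of the animals and the flanked exons are not given in the sources used here. The protocol in the labels describes RNA extracted from lysed tissue and a fragmented, random-primed library, which is not a single-cell protocol, so the capture chemistry is not known from it.

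Per the file headers, the authors made each matrix with Cell Ranger 7.2.0, and its values are whole counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. Per the submitters' processing notes, the genome build was GRCm39. The aligner settings, the annotation release and the rule for calling cells are not given in the sources used here. The deposited matrices list 55357 genes, of which 2342 carry no symbol or share one with another entry and are given by gene identifier. The reference genome at hand is of another build, so no coordinates are printed.

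The library labelled KO held 4896 barcodes and 75024663 UMIs (median 7950 per barcode), and the library labelled WT held 9512 barcodes and 59189995 UMIs (median 2706). The lowest barcode held 501 and 500 UMIs. Barcodes with at least 200 genes and under 20% mitochondrial UMIs passed the filter. The doublet caller Scrublet was run per library with seed 0. Its automatic threshold marked 0.0456% of the library labelled KO and 0% of that labelled WT, which is no working call. The fallback chosen beforehand was used instead: the highest-scoring barcodes at 0.8% per 1000 barcodes were removed, 154 (3.51%) and 633 (7.12%). This left 4233 and 8262 cells.

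Computation used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1 and seed 0. Mitochondrial, ribosomal protein and sex genes, and genes of the fixed lists that are not cell type markers, were left out of the variable genes. Each of the 25 clusters took the name of the fixed marker list (23 lists, 190 genes) with the highest mean standardized level, if at least 3 of its markers were detected in 10% of the cells. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or where its median UMI count was more than 3 times lower than its library's, in a library holding at least 30% of its cells, with none of its own markers leading. No cell type annotation by the authors was used.

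UMIs were summed per library and class, and divided by the class total to give CPM, the usual scaling of counts to the library total, here applied to the total of the class. With 1 library per genotype no test was possible: no p-value, standard error across samples or count of changed genes over all genes is given. Sums carry exact Poisson 95% intervals, ratios of CPM exact conditional binomial 95% intervals, and shares exact Clopper-Pearson 95% intervals. Ratios without free RNA and at equal weight per cluster carry instead the central 95% of Poisson redraws of the counts. All of these cover counting error only and say nothing of the spread between animals. Where a library had 0 UMIs a floor of 3 counts was used for log2 ratios and folds. Genes were compared in classes with at least 50 cells in both libraries, apart from Ecm1 and the ligands of CXCR2, which were summed in every class. For each of 28 fixed gene lists (364 genes, 363 found), the median log2 ratio of members with at least 10 summed UMIs was ranked among 10000 random lists of the same size matched on CPM, as a description of these libraries. List members counted as higher or lower are those whose ratio interval leaves out 1, so these counts cover counting error only. In classes with many UMIs small differences suffice. In epithelial-like cells 10 of 22 autophagy genes were higher and 8 lower, at a median log2 ratio of 0.07. The share of all genes counted in this way is not given. Beside shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out.

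The genes named were set by a rule: the 10 higher and 10 lower in the library labelled KO in epithelial-like and neutrophil-like cells, and 5 of each in monocyte/macrophage-like and T-like cells. They were ranked by the interval bound nearest to a ratio of 1, among genes with at least 50 summed UMIs whose CPM reached 10% of the highest class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor, sex and predicted genes were left out of the ranking. Members of the fixed lists and marker lists, Ecm1, Sqstm1, the ligands of CXCR2 and Cxcr2 could be named in any class. The groups, the filters, the clustering settings, the markers, the gene lists, the rule for named genes, the comparisons and the alternatives were chosen before the data were examined, apart from those said to have been added later. The scoring that turns markers into cluster names was not: it was written once the clusters and their cells per library had been seen. Its clause on depth was worded with 1 cluster in view, which has the marker score of epithelium and ribosomal RNA transcripts among its leading genes. Cells from named immune classes served as the immune denominator, also set at that point.

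The ratio intervals were tested on simulated counts drawn from the pooled profile and the totals of 2 classes, with 200 genes changed. In neutrophil-like cells (4741 genes), 96.2% of the intervals of unchanged genes held 1, and the intervals left out 1 for 64.2% of genes set to a fold of 0.5, 83.6% at a fold of 2 and 100% at a fold of 4. In epithelial-like cells (15473 genes), 95.4% of the intervals of unchanged genes held 1, and 95.5%, 98.5% and 100% left out 1 at the same folds. The simulation had counting error alone, so these shares do not speak of differences between animals.

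Alternatives changed 1 setting at a time: at least 500 genes per cell, under 10% mitochondrial UMIs, no mitochondrial filter, no doublet removal, Leiden resolution 0.5, variable genes including the fixed lists, class calls per cell, immune cells as the denominator, thinning to 1000 UMIs, ratios centred on the median gene, equal weight per cell, and other count minimums (1 and 50 for lists, 20 for named genes). Scrublet was run again after each changed filter, and in the library labelled WT its automatic threshold then worked at 500 genes (337 barcodes removed, 3.98%) and without the mitochondrial filter (455, 4.83%), so these 2 alternatives changed the doublet rule as well. Giving each unnamed cluster the class it scores highest on, equal weight per epithelial-like cluster, the best-filled epithelial-like cluster alone, a wider immune denominator, neutrophil-like cells without the 5 cells of each library richest in granule transcripts, and epithelial-like cells without the 5 of each library richest in Ecm1 were added after the data were seen. Alternatives that left a gene under 10 summed UMIs, the minimum its reported ratio had to meet, were given no ratio, a limit also added after their values were seen.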

Results

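The target gene is reported first, then the cell classes, the ligands of CXCR2, and the neutrophil-like, epithelial-like, monocyte/macrophage-like and T-like cells. Each genotype has 1 library, so every difference below is between 2 libraries, with counting error only. The libraries also differ in the sex genes: Xist, transcribed from the inactive X chromosome, has 96659 UMIs in the library labelled KO and 5 in that labelled WT, and the Y-linked Ddx3y has 0 and 5419.

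Ecm1, which encodes a secreted matrix protein, was not lower in the epithelial-like cells of the library labelled KO. It stood at 40.9 CPM there (95% interval 39.2 to 42.6; 2318 UMIs) and at 34.3 CPM in the library labelled WT (32.2 to 36.5; 984 UMIs), a ratio of 1.19 (1.11 to 1.29). Monocyte/macrophage-like cells held 101 and 105 CPM (ratio 0.96, 0.85 to 1.08), T-like cells 30.2 and 24.6. Fibroblast-like cells, of which the library labelled WT has 11, held 202 and 342 CPM (0.59, 0.41 to 0.87). In neutrophil-like cells it stood at 3.29 and 4.67 CPM.

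The summed ratio does not show the deletion that the genotype labels name. The groups are therefore called the library labelled KO and the library labelled WT throughout. The flanked exons are not given, and a transcript counted at its end may lie outside them, so these values may not check the deletion. The ratio turns with the weighting: it is 0.466 with each cell weighted equally. The 5 cells richest in Ecm1 hold 21.0% of the epithelial-like Ecm1 UMIs in the library labelled KO and 6.30% in that labelled WT, and without them the ratio is 1.00, an alternative added after seeing the data. It is 2.18 with equal weight per cluster, and 0.501 in cluster 2 alone, the epithelial-like cluster best filled in both libraries. At 1000 UMIs per cell, 3.36% (2.64 to 4.22) of 2140 epithelial-like cells labelled KO had an Ecm1 UMI, with 55 shallower cells left out, against 5.98% (4.94 to 7.17) of 1822 labelled WT, with 66 left out. Without thinning the shares were 26.0% and 26.1%; in neutrophil-like cells the thinned shares were 0% and 0.328%.

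**Figure D1:**
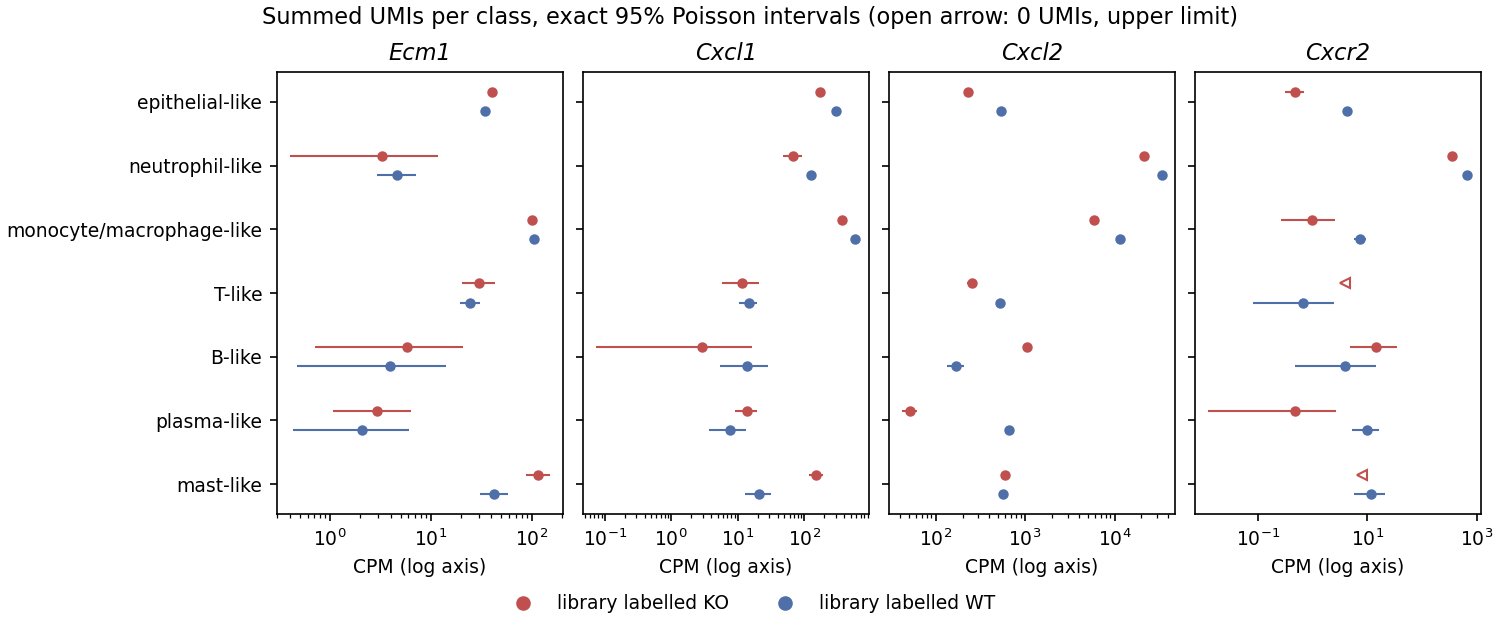
Ecm1, Cxcl1, Cxcl2 and Cxcr2 in 7 cell classes of the 2 libraries, in CPM of summed UMIs on log axes. Lines are exact 95% Poisson intervals of counting error, and open arrows are upper limits where no UMI was counted.

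Neutrophil-like cells made up 4.72% of the cells in the library labelled KO (4.11 to 5.41; 200 of 4233) and 27.1% in the library labelled WT (26.1 to 28.0; 2235 of 8262), a 5.73-fold difference. Of the immune cells alone they were 14.6% (12.8 to 16.6) and 39.0% (37.7 to 40.3), a 2.67-fold difference, while immune cells together were 32.3% (30.9 to 33.7) and 69.4% (68.4 to 70.4) of cells. Epithelial-like cells were 51.9% (50.3 to 53.4) and 22.9% (21.9 to 23.8). Endothelial-like cells were 24.0-fold and fibroblast-like cells 18.8-fold more frequent in the library labelled KO (4.94% and 0.206%; 2.50% and 0.133%).

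Among the other immune classes, T-like cells were 6.38% and 13.6% of all cells in the libraries labelled KO and WT, monocyte/macrophage-like cells 11.8% and 15.8%, conventional dendritic-like cells 0.992% and 4.64%, mast-like cells 1.65% and 3.18%. Plasma-like cells were 3.47% and 1.66%, B-like cells 3.21% and 3.22%. The denominator turns some of these: of immune cells, monocyte/macrophage-like cells were 36.4% and 22.8%, T-like cells 19.8% and 19.6%, mast-like cells 5.12% and 4.59%. B-like cells were 9.95% and 4.64% of immune cells, and plasma-like cells 10.8% and 2.39%. Conventional dendritic-like cells, at 3.07% and 6.68%, stayed lower in the library labelled KO. Unnamed clusters held 8.41% and 7.44%, most of them in cluster 4 (7.09% and 4.21%), whose leading genes include ribosomal RNA transcripts. The barcodes labelled KO were deeper, with a median of 2848 and 1912 UMIs in neutrophil-like cells and 20571 and 11803 in epithelial-like cells.

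**Figure D2:**
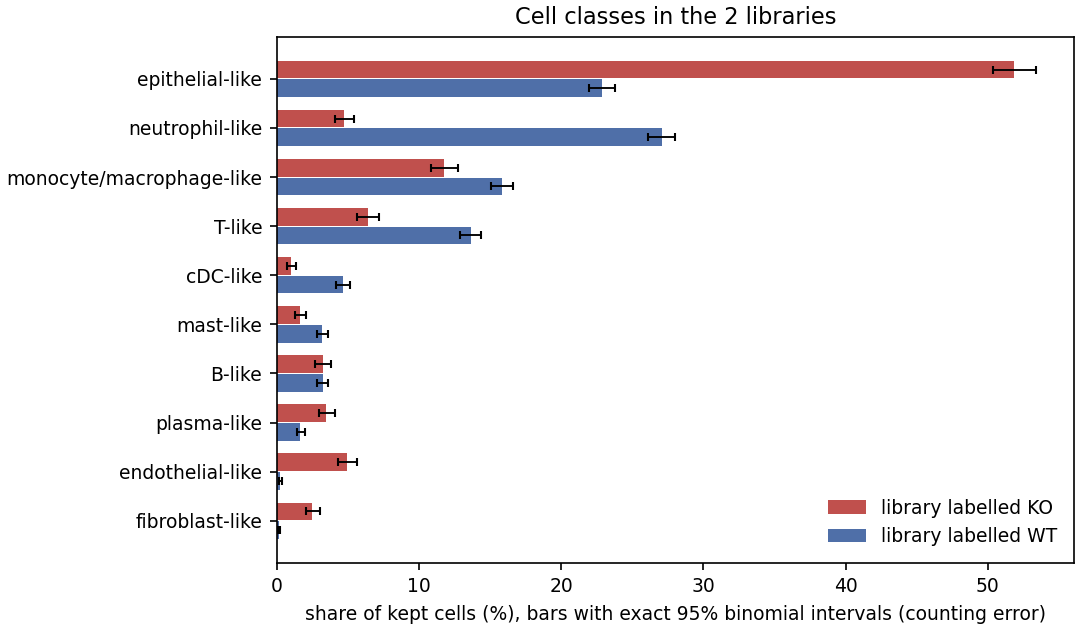
Share of kept cells in each of 10 cell classes in the 2 libraries. Error bars are exact 95% binomial intervals of counting error.

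Cxcl1 and Cxcl2, chemokines that bind CXCR2, the receptor that draws neutrophils into tissue, were lower in epithelial-like and monocyte/macrophage-like cells of the library labelled KO, but not in every class. In epithelial-like cells Cxcl1 stood at 170 CPM (167 to 174) against 295 (288 to 301), a ratio of 0.58 (0.56 to 0.59), and Cxcl2 at 232 against 539, a ratio of 0.43 (0.42 to 0.44). Without the free RNA expected from neutrophils and macrophages, an estimate made after seeing the data, the Cxcl2 ratio is 0.658 (0.634 to 0.679). Monocyte/macrophage-like cells, the richer source of Cxcl2 per UMI, held 365 and 584 CPM of Cxcl1 (0.62) and 5821 and 11460 CPM of Cxcl2 (0.51). Neutrophil-like cells held 21223 and 33814 CPM of Cxcl2 (0.63). Cxcr2 itself stood at 352 and 662 CPM in neutrophil-like cells (0.53, 0.46 to 0.61); it is among the leading genes of cluster 9, to which most of them belong.

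Not every ligand or class followed. Cxcl5 was 1.16-fold higher in epithelial-like cells of the library labelled KO, but 0.643 with each cell weighted equally and 0.950 in cluster 2 alone. Cxcl3 had a ratio of 0.62 there, but 1.16 with equal weight per cluster; in neutrophil-like cells it had 0.90, and 1.05 with each cell weighted equally. In mast-like cells the list of ligands was higher in the library labelled KO, with 3 of 4 genes higher and 0 lower (median log2 ratio 2.45, percentile 99.9): Cxcl1 7.29-fold (152 and 20.8 CPM), Cxcl3 4.08-fold and Cxcl5 49.3-fold (71 and 3 UMIs), with 68.6%, 89.4% and 50.7% of the UMIs labelled KO in 5 cells, beside the epithelial marker Epcam at 1784 and 125 CPM in these cells. In B-like cells Cxcl2 was 6.33-fold higher (4.99 to 8.10; 364 and 86 UMIs), with 97.8% of the UMIs labelled KO in 5 cells, but had a ratio of 0.503 without doublet removal, and of 0.441 without the mitochondrial filter, where the doublet rule changed as well; S100a8 stood at 817 and 203 CPM there. Fibroblast-like cells held 1637 CPM of Cxcl1 and 541 of Cxcl5 in the library labelled KO, and 176 and 52 (51.8) in that labelled WT, where they number 11. Cxcl1 was lower in 5 of the 8 epithelial-like clusters, higher in 1, and the interval held a ratio of 1 in 2; Cxcl2 was lower in 7 of 8. At 1000 UMIs per cell, 11.6% and 16.4% of epithelial-like cells had a Cxcl1 UMI (53.5% and 48.5% unthinned), and 1.53% and 0.925% of T-like cells. In monocyte/macrophage-like cells these shares were close, at 18.4% (15.0 to 22.2) and 19.1% (17.0 to 21.3), and 31.9% and 30.2% unthinned. RNA of neutrophils was spread more widely in the library labelled WT: S100a8, a neutrophil marker, stood at 41.6 and 370 CPM in epithelial-like cells.

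Sqstm1, which encodes the autophagy receptor p62, was lower in the library labelled KO in all 4 main classes: 113 and 135 CPM in epithelial-like cells (0.83, 0.80 to 0.87), 188 and 343 in monocyte/macrophage-like cells (0.55), 138 and 213 in T-like cells (0.65), and 133 and 188 in neutrophil-like cells (0.71). The autophagy list as a group stayed near a ratio of 1, with median log2 ratios of 0.07, -0.03, 0.14 and -0.19 in the same order.

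In neutrophil-like cells the list for neutrophil extracellular traps (NETs) was higher in the library labelled KO and the activation list lower. The NET list had a median ratio of 1.26. It was 1.12 without the 5 cells of each library richest in granule transcripts, an alternative added after seeing the data. That 1.12 equals the ratio of its member Ltf, whose interval holds 1 (0.34 to 2.87). Of 15 measured NET genes, which include Camp and Ltf, 7 were higher and 3 lower, with a median log2 ratio of 0.33 (percentile 98.0 among matched random lists). Epithelial and goblet markers had higher medians in this class: of 10 epithelial markers 5 were higher and 0 lower (median 0.57, percentile 99.3), with Epcam at 110 and 56.4 CPM, and of 7 goblet markers 3 were higher and 3 lower (0.72, percentile 99.1). Erythroid markers went the other way, with 4 of 4 lower (-2.92, percentile 0). Among the NET genes are Cyba and Ncf4, subunits of the NADPH oxidase (961 and 525 CPM, ratio 1.83; 326 and 174, ratio 1.87), and Lcn2, a granule protein that binds iron carriers (3089 and 2337, ratio 1.32), which epithelial-like cells also hold (319 and 642). Padi4, whose enzyme citrullinates histones in NET release, stood at 74.1 and 70.4 CPM (1.05, 0.75 to 1.44), while Mmp9 had a ratio of 0.84. Of 23 activation genes 15 were lower and 4 higher, with a median of -0.45 (percentile 1.25): Ptgs2, the inducible cyclooxygenase (583 and 2035 CPM, ratio 0.29), Vegfa (44.4 and 157, ratio 0.28) and Tnfaip3, a brake on NF-kB (436 and 1139, ratio 0.38). Nfkbia and Tnf went the other way, with ratios of 1.77 and 1.54.

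The granule list, which shares Camp, Ltf, Lcn2, Mmp9 and Cybb with the NET list, was higher as well. It had 9 of 16 genes higher, 4 lower and a median log2 ratio of 0.38, but this rests on few cells. Camp, Ltf and Ngp, granule genes of immature neutrophils, were 150-fold, 25.4-fold and 11.9-fold higher in the library labelled KO, where 5 cells held 92.1%, 95.8% and 86.2% of their UMIs. Chil3 was 43.0-fold higher, with 89.7% in 5 cells. Lyz2 (lysozyme) was 2.56-fold higher, with 11.9% in 5 cells. Without the 5 cells of each library richest in Camp, Ltf and Ngp, an alternative added after seeing the data, the ratios were 14.5 for Camp (7.08 to 30.9), 1.12 for Ltf (0.34 to 2.87), 1.90 for Ngp (1.52 to 2.35) and 4.70 for Chil3 (0.73 to 24.2; 3 and 5 UMIs). The granule list then had a ratio of 0.878.

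The other genes named by rule in neutrophil-like cells were lower in the library labelled KO for Fos, an immediate early gene (541 and 3562 CPM, 6.58-fold), Thbs1 (701 and 3732, 5.32-fold), Dgat1, which makes triglycerides (155 and 734, 4.74-fold), Ncapg2 (1 and 261 UMIs), Gpr65 (7.24-fold), Tmem156 (6.50-fold), Kcnj2 (5.16-fold), Myadm (4.48-fold) and Tgif1 (3.91-fold). Higher were Klf2, a quiescence factor (2039 and 734 CPM, 2.78-fold), Clic1 (869 and 289, 3.01-fold), Mdh2 (3.26-fold) and Arf2 (9.11-fold). Transcripts tied to ribosomal RNA were higher too: Rn18s-rs5 at 61171 and 4924 CPM (12.4-fold), Lars2 (5.08-fold) and Mir6236 (5.73-fold). Of the interferon list 6 of 17 genes were lower and 1 higher (median -0.59), of the NF-kB list 9 of 16 lower and 3 higher (-0.41). The median of all genes with at least 50 UMIs was -0.16 in this class.

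**Figure D3:**
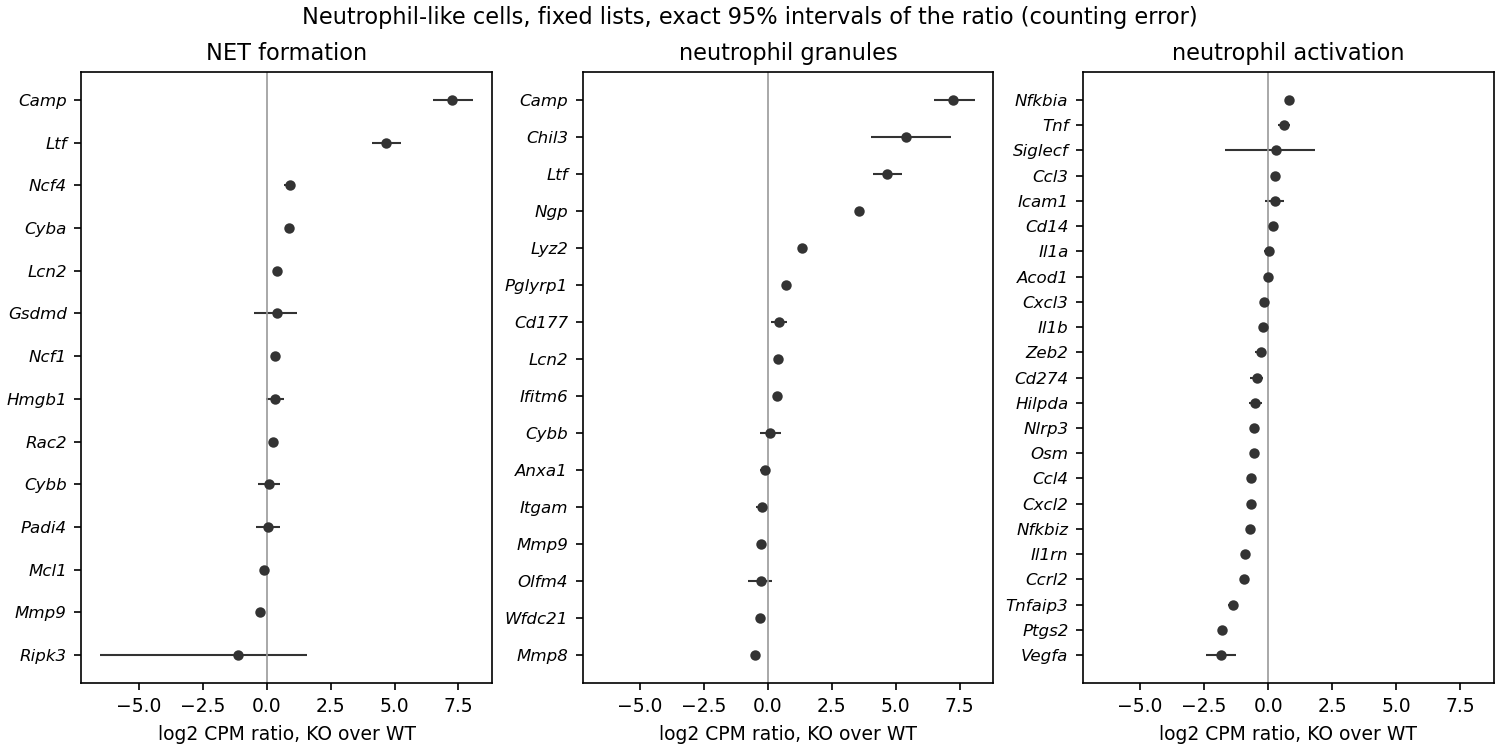
Log2 CPM ratio, library labelled KO over library labelled WT, of the members of 3 fixed lists in neutrophil-like cells. Lines are exact 95% intervals of counting error; genes with no UMI in a library and 1 further member of the NET list are not drawn.

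Epithelial-like cells of the library labelled KO had lower interferon, antimicrobial and hypoxia genes and higher cell cycle genes. Of 20 interferon genes 16 were lower and 1 higher (median log2 ratio -1.25), such as Ifit1 at 12.7 and 64.3 CPM. Of 15 antimicrobial and injury genes 10 were lower and 5 higher (-0.85): Duox2, an epithelial oxidase (52.6 and 163 CPM), Reg3g, an antimicrobial lectin (139 and 314), and Lcn2 (319 and 642) were lower, Krt7 (397 and 251) higher. Of 15 hypoxia and glycolysis genes 12 were lower and 2 higher (-0.51), among them Vegfa (28.5 and 82.5). Of 20 cell cycle genes 15 were higher and 2 lower (0.42), with Mki67, a proliferation marker, at 130 and 66.6 CPM. Of 10 goblet genes 8 were lower and 2 higher (-0.62), and of 12 colonocyte genes 8 and 2 (-0.82). As shares of all cells, goblet-like clusters were not rarer in the library labelled KO, however. Cluster 18, led by goblet genes such as Zg16 and Muc2, held 3.83% of cells labelled KO and 0.399% labelled WT. Its cells were shallow, with medians of 3317 and 3126 UMIs, so they weigh little in the summed UMIs. Cluster 5, led by defensin genes and also scoring highest on goblet markers, held 2.74% and 2.60% of all cells. Within the epithelial-like class it was rarer in the library labelled KO, with 116 of 2195 cells against 215 of 1888.

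The list of intestinal stem and Wnt genes was split, with 7 of 17 higher and 9 lower (-0.07); Lgr5, the stem cell marker, stood at 89.2 and 77.4 CPM. Lists of neutrophil and macrophage genes were lower as well in these cells, beside S100a8 at 41.6 and 370 CPM: 20 of 23 activation genes and 15 of 16 inflammatory macrophage genes. Markers of cells more frequent in the library labelled KO were higher: 5 of 7 fibroblast markers, with 1 lower (1.49), and 5 of 10 endothelial markers, with 2 lower (0.57). Different clusters make up the class: in the library labelled KO mostly clusters 2 (18.9% of cells) and 7 (12.5%), in that labelled WT clusters 1 (6.71%) and 2 (6.33%). Cluster 1 was 2.46% of cells labelled KO. Its cells were far shallower in the library labelled WT, with a median of 2906.5 UMIs against 28632.5 in that labelled KO.

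Of the genes named by rule, Saa1 and Saa2, acute phase proteins, were 12.1-fold (45.4 and 549 CPM) and 12.5-fold lower in the library labelled KO; Saa1 is among the leading genes of cluster 1. Mdk, a heparin-binding growth factor, was 27.5-fold lower, Dlk1 17.2-fold, Ces2f 14.3-fold, Prss27 13.7-fold, Defa43 12.6-fold (80.6% of the UMIs labelled WT in 5 cells) and Ggt1 12.5-fold, as were 2 transcripts known by identifier alone, by 16.6-fold and 14.0-fold. Higher were the gut hormone genes Gcg (611 UMIs and 1), Insl5 (110-fold), Pyy (58.6-fold) and Ppy (78 UMIs and 0), but 1 cell held 98.2% of Gcg and 97.3% of Insl5 UMIs, 5 cells 94.0% of Pyy UMIs and 1 cell 88.5% of Ppy UMIs. Without doublet removal the ratios were 1.61 for Gcg, 4.51 for Insl5 and 7.55 for Pyy, and Ppy had under 10 UMIs. Krt14, a basal keratin, was 5.74-fold higher (58.8 and 10.2 CPM), Hao2, a leading gene of cluster 0, 9.95-fold, Tmem174 10.6-fold and Rn18s-rs5 5.41-fold. Gria3 had 98 UMIs and 1, and Sprr2e 50 and 0, with 76% in 1 cell.

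**Figure D4:**
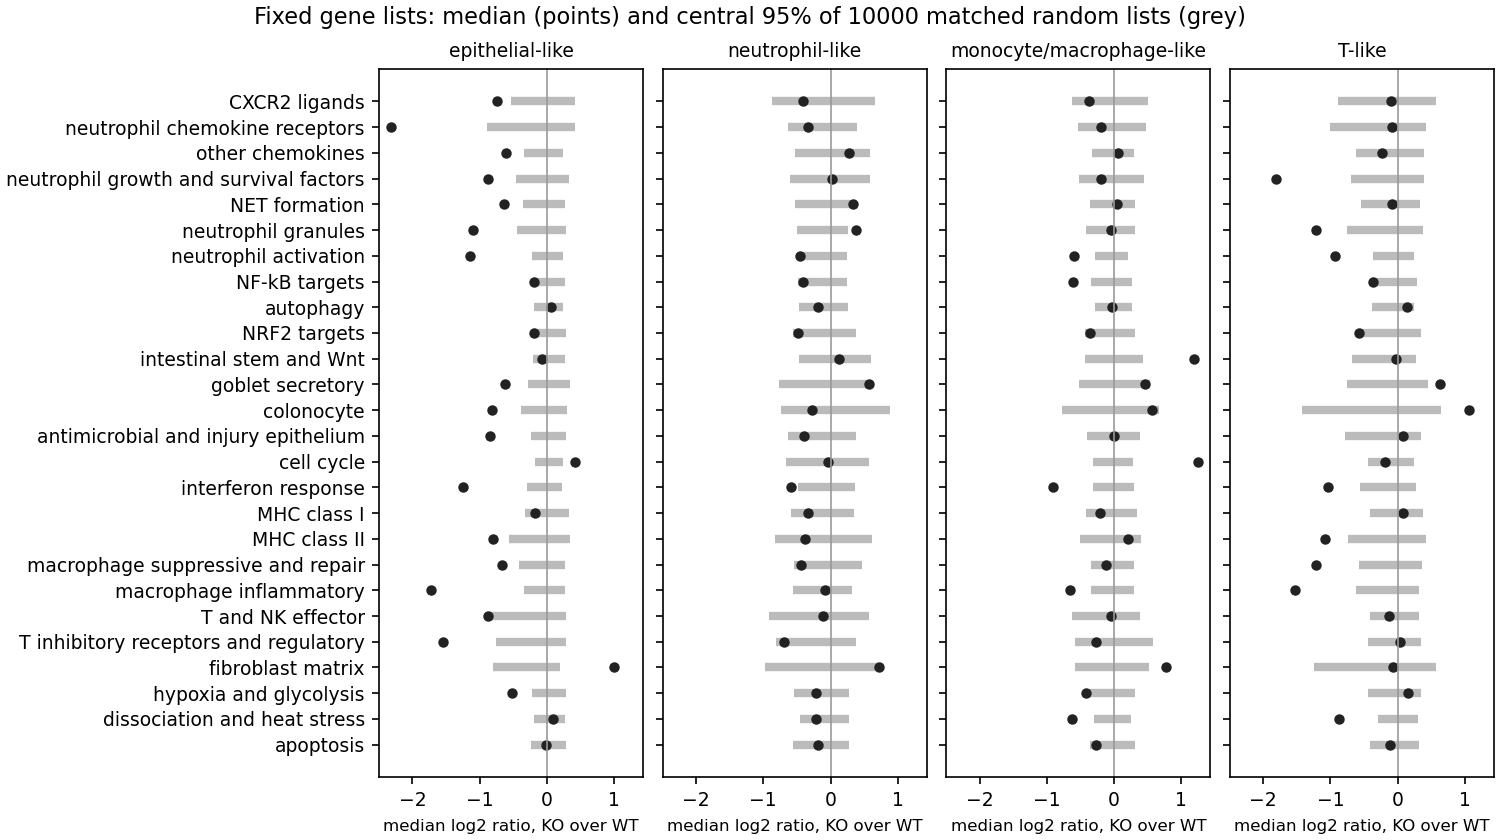
Median log2 CPM ratio, library labelled KO over library labelled WT, of each fixed gene list in 4 cell classes (points). Grey bars span the central 95% of the medians of 10000 random lists matched on size and CPM.

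Monocyte/macrophage-like cells of the library labelled KO had higher cell cycle genes and lower inflammatory genes. The class joins cluster 6, led by Chil3, and cluster 19, led by C1qa, in a different mix. They held 222 and 276 cells in the library labelled KO, and 861 and 445 in that labelled WT. The values below are sums over both clusters, so a change of mix cannot be told apart from a change within a cluster. Of 20 cell cycle genes 19 were higher and none lower (median log2 ratio 1.25), with Mki67 at 76.4 and 34.4 CPM. Of 16 NF-kB genes 14 were lower and 0 higher (-0.61), and of 16 inflammatory macrophage genes 11 were lower and 5 higher (-0.66). Tnf and Il6, inflammatory cytokines, stood at 148 and 647 CPM (4.36-fold lower) and at 24.8 and 122 (4.90-fold lower). Of 20 interferon genes 14 were lower and 1 higher (-0.90), while of 8 MHC class II genes 6 were higher and 1 lower (0.20).

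The dissociation and heat stress list was lower with them, with 12 of 18 genes lower and 4 higher (-0.63). S100a8 stood at 170 and 565 CPM and the epithelial marker Epcam at 166 and 40.2 CPM in these cells, and the stem and Wnt list was higher (1.19). Of 10 epithelial markers 9 were higher and 0 lower (1.40), of 8 endothelial markers 4 and 0 (1.26), and of 10 neutrophil markers 10 were lower (-0.88). The cell cycle list was also higher in plasma-like (1.68) and mast-like cells (0.68), where the median of epithelial markers was 2.09 and 3.38. In T-like and neutrophil-like cells the cell cycle list was not higher (-0.19 and -0.04), although epithelial markers were. How far epithelial RNA adds to the cell cycle values was not tested. The other genes named by rule were Cd209a (0 and 137 UMIs, 50.4% of the latter in 5 cells), Art2a (1 and 50) and S1pr3 (6.94-fold), lower, and Rn18s-rs5 (9.16-fold), H1f5 (5.65-fold, 65.4% of UMIs in 5 cells), Smagp (5.48-fold), Sox17 (13.6-fold, 57.7% in 5 cells) and Il22 (65 UMIs, all in 1 cell, and 6), higher.

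In T-like cells the cytotoxic genes Gzma and Gzmb were 2.49-fold and 2.07-fold higher in the library labelled KO (1265 and 508 CPM; 757 and 365), with 87.7% and 48.1% of the UMIs labelled KO in 5 cells, and Ifng, the cytokine of type 1 responses, was lower (36.5 and 129 CPM, ratio 0.28; 54.3% of the UMIs labelled KO in 5 cells). The T-like class joins clusters 12, 17 and 22, with 80, 147 and 43 cells labelled KO, and 372, 524 and 230 labelled WT. Ifng is among the leading genes of cluster 22, so a change of mix cannot be told apart from a change within a cluster. Unnamed cluster 21, with Il17a and Gzmb among its leading genes, lies outside the class. The effector list as a whole was split, with 4 of 15 genes higher and 4 lower (median log2 ratio -0.13), as was the list of inhibitory receptors and regulatory genes (0.03). Of 17 interferon genes 7 were lower and 2 higher (-1.04). Il17f stood at 10.4 and 94.4 CPM (9.05-fold lower), and Egr1, an immediate early gene, was 4.26-fold lower.

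Beside these, 13 of 18 dissociation and heat stress genes were lower and 2 higher (-0.87), and S100a8 stood at 21.9 and 201 CPM. Inflammatory macrophage genes (7 of 12 lower, 1 higher, -1.53) and monocyte/macrophage markers (3 of 9 lower, 0 higher, -1.05) were lower in these cells as well, while epithelial markers (5 of 10 higher, 0 lower, 0.64) and goblet markers (4 of 6 higher, 2 lower, 1.07) were higher. The counts of some genes named by rule rest on few cells: 1 cell held 90% of the Il17f UMIs in the library labelled KO and 5 cells 85.6% in that labelled WT, and Gzmd (0 and 53 UMIs) was seen in 2 cells labelled WT. Lpcat4 had 1 and 90 UMIs and Vmn2r89 had 0 and 54. Higher were Rn18s-rs5 (11.1-fold), Lars2 (4.69-fold), Mir6236 (4.54-fold), Ermn (4.18-fold, 52% of UMIs in 5 cells) and Ltb4r1, a receptor of leukotriene B4 (3.79-fold).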

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

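The tests below were chosen after the results were seen, among them shallow neutrophils as the whole cause and equal weight per epithelial-like cluster; only the bounds for shallow neutrophils as a cause in part and for Cxcl2 at equal weight were written before their values were seen.

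The sex genes separate the libraries, a difference the labels do not give. Xist has 96659 UMIs in the library labelled KO and 5 in the library labelled WT. The Y-linked genes show the reverse: Ddx3y has 5419 UMIs in the library labelled WT and 0 in that labelled KO, Eif2s3y 2373 and 0, Uty 1787 and 0, and Kdm5d 1013 and 4. Sex and genotype label therefore differ together, and every difference between the libraries is also one between cells with and without a Y chromosome.

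The lower share of neutrophil-like cells in the library labelled KO was weighed first. An equal under-recovery of all immune classes is argued against, since the share within immune cells still had a ratio of 0.375 (0.323 to 0.434). Loss of the shallowest neutrophils below the UMI minimum was weighed for the share of immune cells, by which 62.5% of the neutrophils were missing. The larger gap in the share of all cells was not weighed this way. Scaled by the depth ratio of other immune classes (1.36), the missing cells would fall below 2800 UMIs. As the whole cause, such a loss would leave under 10% of the neutrophil-like cells labelled KO below that depth. In the data 47.5% (40.4 to 54.7, 95 of 200) were. With no loss and that depth ratio, 62.5% would lie below it, as the depth was set from that share of the cells labelled WT. A loss of part of the shallow neutrophils cannot be told apart and stays open, because the bound set beforehand against it, over 50%, was not met. The UMI minimum was alike, with 501 and 500 UMIs in the lowest barcode, so it alone would take fewer of the deeper cells labelled KO. Barcodes with under 200 genes, which were given no class, numbered 218 labelled KO and 98 labelled WT. Sex and the handling of the tissue cannot be told apart from genotype, as they vary together: Rn18s-rs5, a transcript tied to ribosomal RNA, had a ratio of 12.4 in neutrophil-like cells, and endothelial-like and fibroblast-like cells differ in share as well.

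The Ecm1 level in epithelial-like cells labelled KO was weighed next. Free RNA from other cells is argued against as its source, since the level was 12.3 times (6.69 to 25.7) that of B-like, plasma-like and neutrophil-like cells of the same library, 3.32 CPM from 10 UMIs. An exchanged label alone is argued against too, since it would put the deletion in the library labelled WT, where the epithelial-like level was 8.54 times (5.79 to 13.1) that of the same 3 classes, with 26 UMIs. The mix of clusters cannot be told apart from a difference within clusters: Ecm1 was lower in 1 of 8 epithelial-like clusters, higher in 4, and the interval held a ratio of 1 in 3. Transcript ends counted outside the deleted part and incomplete recombination, with or without an exchanged label, stay open for the 2318 UMIs, as these counts cannot be told apart by exon or allele.

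Lower Cxcl1 and Cxcl2 in epithelial-like cells labelled KO were weighed last. Free RNA of neutrophils and macrophages is argued against as the whole cause: without the amount their markers predict, the ratios were 0.584 (0.568 to 0.601) and 0.658 (0.634 to 0.679). For Cxcl2, however, that amount was 224 CPM in the library labelled WT and 24.2 in that labelled KO. The intervals hold the amount fixed, so its own uncertainty is not in them. The macrophage part rests on C1q genes, which are among the leading genes of cluster 19 but not of cluster 6. In the library labelled WT cluster 6 is the larger, with 861 cells against 445. Other proportions of epithelial-like clusters are argued against as the whole cause too, with ratios of 0.655 (0.630 to 0.682) and 0.508 (0.490 to 0.526) at equal weight per cluster. Free RNA and cluster proportions were each weighed with the other left in, so both together were not weighed and stay open. Genotype, sex and tissue handling stay open and untested here.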

How the results depend on the processing

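Equal weight per epithelial-like cluster, cluster 2 alone, the wider immune denominator, the class of highest score for unnamed clusters and the removal of 5 granule-rich or Ecm1-rich cells were chosen after seeing the data, as was leaving out 8 alternatives with under 10 summed UMIs for the gene. Of 2151 alternative values for 219 results, 1751 stayed within the interval of the reported value, 374 moved outside it in the same direction or from an interval holding 1, and 26 reversed. Naming the unnamed clusters by their highest score, which bears on the cluster names written once shares were known, reversed no value, with 85 staying and 14 moving; Ecm1 and Cxcl1 in epithelial-like cells then had ratios of 1.19 and 0.585.

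The neutrophil-like share was lower in the library labelled KO in every alternative tried. It moved from a ratio of 0.175 to 0.375 of immune cells and to 0.377 with unnamed clusters of T markers added to them. Immune cells themselves were 32.3% of the library labelled KO and 69.4% of that labelled WT, which raises these ratios. Epithelial-like Cxcl1 stayed lower, at 0.605 without doublet removal, 0.640 with cells weighted equally, 0.655 with clusters weighted equally and 0.496 in cluster 2. Ecm1 there reversed to 0.466 with cells weighted equally and 0.501 in cluster 2, and moved to 2.18 with clusters weighted equally and to 1.00 without the Ecm1-rich cells. The NET list moved to 1.40 when centred on the median gene and to 1.12 without the granule-rich cells. That 1.12 equals the ratio of its member Ltf, which then had 5 UMIs labelled KO and 35 labelled WT. The interval of Ltf was 0.34 to 2.87 and holds 1. In neutrophil-like cells the activation list moved in none of its alternatives. For the moves of Ecm1, Cxcl1 and the NET list the cause was not tested.

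The other reversals follow, and the cause was not tested. As shares of immune cells: T-like 1.01, mast-like 1.12, monocyte/macrophage-like 1.60. At 500 genes and without the mitochondrial filter the doublet rule changed too, in the library labelled WT. Cxcl2 in B-like cells, reported at 6.33: 0.441 without a mitochondrial filter, 0.503 without doublet removal. Cxcl3 in epithelial-like cells: 1.16 with clusters weighted equally; in neutrophil-like cells 1.00 when centred and 1.05 with cells weighted equally. Cxcl5 in epithelial-like cells: 0.643 with cells weighted equally, 0.950 in cluster 2. Ppbp in monocyte/macrophage-like cells: 0.994 without doublet removal.

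Lists in epithelial-like cells: stem and Wnt 1.02 with cells and 1.01 with clusters weighted equally, fibroblast matrix 0.938 at 50 UMIs or more. Granules in neutrophil-like cells: 0.978 with cells weighted equally, 0.878 without the granule-rich cells. In monocyte/macrophage-like cells: goblet 0.891 under 10% mitochondrial UMIs and 0.956 without that filter, suppressive genes 1.08 with variable genes including the lists. In T-like cells: growth factors 1.34 and activation 1.00 under 10% mitochondrial UMIs, granules 1.03 with members from 1 UMI, suppressive genes 1.09 at 500 genes and 1.17 without the mitochondrial filter.

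No paired analysis was possible because each genotype has 1 library and nothing in the labels ties them. Depth limits the neutrophil-like class more than the epithelial-like class, the only pair simulated: in simulated counts 64.2% of genes at a fold of 0.5 had an interval leaving out 1, against 95.5% in epithelial-like cells.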

Other observations

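The values in this part were chosen after they were seen, apart from the lists and marker classes they come from. Within the monocyte/macrophage-like class, cluster 6, led by Chil3, F13a1 and Vcan, held 5.24% of cells in the library labelled KO and 10.4% in the library labelled WT. Cluster 19, led by C1qa and Apoe, held 6.52% and 5.39%. Cluster 10, neutrophil-like cells led by Ccl3 and Il36g, held 0.425% and 2.88%.

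Unnamed cluster 21, led by Trdc and Il17a, held 1.13% and 2.61%, and unnamed cluster 23, with Il13 and Gata3 among its leading genes, 0.189% and 0.617%.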
